A study of Mus musculus with 4 samples.

How the data were processed

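Total RNA from 4 mouse embryonic stem cell samples, grown on feeder fibroblasts, was labelled with biotin and hybridised to Illumina MouseWG-6 v2 bead arrays, per the labels' protocols and the file headers. Both 2i-derived samples were measured on 2 arrays each and both standard-derived samples on 1 array each. The deposited bead intensity is the mean bead signal of a probe on 1 array on a linear scale, summarised with Illumina GenomeStudio 1.0.6 with normalization set to none, per the file headers. The deposited detection score of each probe runs from 0 to 1 and rises with its signal, and the detection p was taken as 1 minus this score. A deposited table of log2 values, with 1 row per target name, was used as an alternative. The method behind these log2 values is not given in the sources used here. Setting them against the intensities showed that they equal the mean, over the probes and arrays of a target, of quantile-normalized log2 intensity, with a Pearson r across 31458 targets of 1.0 in each of the 4 columns and 95% of differences within 0.002. Their medians were 5.91, 5.91, 5.91 and 5.92.

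The intensities were background corrected from the detection p, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 (R 4.3.3, offset 16). Arrays of the same sample were averaged after normalization, so that each sample counts once. A probe was kept where its mean detection p lay under 0.05 in at least 2 of the 4 samples, and each gene was represented by its detected probe with the highest mean over the 4 samples, which left 14569 genes. Between 42.3% and 43.9% of the 45281 probes were detected per array, with median intensities of 59.3 to 63.2, so detection and the number of arrays limit the precision. A gene undetected on every array of a group has only a bound there. Its fold is given as at least N-fold, from the mean of the bright group against the mean of, per array, the higher of the lowest value among detected probes and the probe's own value. Of the 31490 target names, 13430 matched a current symbol, 5593 matched through a unique synonym, 12437 kept the file's name and 30 had been turned into dates or numbers by a spreadsheet and were left out, with their 46 probes. Names, chromosomes and the order of neighbouring genes come from an annotation of GRCm38.p6. No build is named in the sources used here, so no coordinates are given.

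The 2i-derived samples were compared with the standard-derived samples with limma (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg over all genes tested), and genes with an adjusted p under 0.05 are called. Strain and passage number were not entered, since either would have left the spread to 2i-RFP+ and 2i-RFP- alone. Entering strain gives R1 a term of its own, so that the difference becomes the one without R1. In 20 simulated data sets with 2 samples against 2 and 14569 genes, 0.0439% of unchanged genes were called, and 19.5%, 77.9%, 92.0% and 96.9% of genes changed by 1, 2, 3 and 4 log2 units. Each simulated gene varied alike in both groups. In the data the root mean square difference was 0.164 within the 2i-derived group and 0.553 within the standard-derived group. The simulated rates do not cover such unequal spread. Gene lists fixed before the data were examined were tested with limma's camera with a preset correlation of 0.01, adjusted over the 21 lists with at least 5 tested members. In the same simulations a list shifted by 1 log2 unit was called in 20 of 20 runs and other lists in 0 of 400 tests. The simulated genes were drawn independently, so these counts do not cover lists whose members vary together. The 24 lists are naive pluripotency, core pluripotency, primed epiblast, germline and primordial germ cell, primitive and visceral endoderm, trophectoderm, primitive streak and mesoderm, neural ectoderm, fibroblast feeder, MAPK-ERK feedback, WNT beta-catenin targets, LIF-STAT3 targets, BMP-ID and TGFb-Nodal targets, imprinted genes, 2-cell-like genes, DNA methylation machinery, X and Y sex markers, p53 targets, glycolysis and hypoxia, sterol synthesis, amino acid and ER stress response, interferon response and MHC, the Hox cluster, and the mitotic cell cycle.

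The comparisons of 2i-RFP+ with 2i-RFP- and of AFF204#21 with R1 have 1 sample on each side and no test. Genes detected in at least 1 of the 2 samples are counted where they differ at least 2-fold, and each list's median is placed among 10000 random lists of the same size matched on mean expression. The random lists draw genes independently, so the percentiles do not cover lists whose members vary together. Named genes follow a rule fixed before the data were examined. It takes the 12 called genes with the largest fold change in each direction whose groups do not overlap, filled to 12 by the smallest p, leaving out predicted genes. It takes up to 4 members of each list by smallest p, and always Prdm1, Pou5f1, Nanog, Sox2, Zfp42, Klf4, Dppa3, Xist, Ddx3y and Col1a1. For each single pair it takes the 8 largest differences in each direction among genes detected in both samples and up to 4 in each direction detected in only 1 of them. Not every gene the rule takes is printed, and some genes outside it are. Among the latter are Rhox6, Rhox10, Rhox13, Sox7, Igf2, H19, Kcnq1ot1, Nap1l4, Tssc4, Taf6, Wdr82 and some feedback genes of MAPK-ERK signalling. Their choice was not fixed in advance. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.

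Alternatives changed 1 step at a time, except that the stricter detection changed both the threshold and the number of samples, and that the deposited log2 table both lacks background correction and averages all probes. They were no background correction, median scaling in place of quantile normalization, the deposited log2 table, no detection filter, detection at p under 0.01 in all 4 samples, the mean of a gene's detected probes, only the first array of each sample, leaving out each sample, no intensity trend, a robust trend, an adjusted p under 0.10, a 2-fold minimum, camera with an estimated correlation, fry, and the median of a list in place of its mean. Intervals of medians over genes come from 1000 bootstrap draws of genes and cover the spread among genes only.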

Results

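Gene expression was measured in 4 mouse embryonic stem cell samples to compare lines established under 2i with lines established under standard conditions. 2i usually denotes a medium with inhibitors of MEK and of GSK3, and per the labels all lines were kept without it after derivation. The 2i-derived group held 2 samples, titled 2i-RFP+ and 2i-RFP-, both C57/B6 at passage 5. The standard-derived group held AFF204#21, C57/B6 at passage 11, and R1, strain 129 at passage 26, titled AFF204#21-A and R1-A and given here without the ending. Both 2i-derived samples had fewer passages than either standard-derived line, so derivation and passage cannot be told apart. The labels do not say what RFP reports, nor whether the 2i-derived samples are separate derivations. The array names of both 2i-derived samples share the stem 2imES#1, so they may come from the same line. Between 19143 and 19865 of the 45281 probes were detected per array. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples. Within the 2i-derived group this spread may be technical. Within the standard-derived group it is the difference between lines of unlike strain and passage.

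The 2i-derived samples were nearly alike, whereas the standard-derived lines differed from each other about as much as from the 2i-derived samples. The root mean square difference was 0.164 log2 units between 2i-RFP+ and 2i-RFP- and 0.553 between AFF204#21 and R1. It was 0.474 and 0.477 between the 2i-derived samples and AFF204#21, the other C57/B6 line, and 0.636 and 0.644 between them and R1. The mean of the 4 distances between groups was 1.01 times that between both standard-derived lines. Repeat arrays of the same sample differed by 0.220 for 2i-RFP+ and 0.191 for 2i-RFP-, from which 0.146 would be expected between the averaged samples, against the 0.164 observed.

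The genes Rhox2a, Rhox4b and Rhox1 of the X-linked Rhox homeobox cluster, expressed in the reproductive tract and germ cells, were higher in the 2i-derived lines, as was Xist, the RNA that coats the inactive X chromosome. Rhox2a was 11.7-fold higher, with 8.94 ± 0.03 (SD, n = 2) against 5.38 ± 0.45 log2 units (n = 2, detected on 1 of the 2 standard-derived arrays), Rhox4b at least 5.95-fold and Rhox1 at least 3.33-fold higher. Xist was 4.03-fold higher, with 8.69 ± 0.07 against 6.68 ± 0.07, and its other probes gave log2 differences of 1.12 to 1.97. Rhox2 and Rhox4 genes have near-identical copies, so their probes may not tell copies apart, and a second Rhox4b probe gave a log2 difference of 1.09. Other genes of the cluster went both ways without passing the threshold of limma's test. Log2 differences were 3.802 for Rhox6, 3.68 for Rhox9 and 1.359 for Rhox5 (adjusted p = 0.1481, 0.127 and 0.1156). They were -1.76 for Rhox10 and -1.04 for Rhox13 (adjusted p = 0.177 and 0.269). Rhox6 had 2.324 against AFF204#21 and 5.281 against R1. Outside the cluster, the cytokine Osm was 4.69-fold, the acetyl-CoA synthetase Acss1 3.67-fold, spermine synthase Sms 2.61-fold and Tdrd12, of the piRNA pathway, 2.12-fold higher. The secreted synaptic protein Cbln4 was at least 2.88-fold higher. Lower in the 2i-derived lines were the Y-linked translation factor gene Eif2s3y (23.7-fold, 6.13 ± 0.18 against 10.69 ± 0.54), Gad1, which makes GABA, the homeobox gene Gbx2 (10.6-fold, 9.47 ± 0.03 against 12.87 ± 0.19), the amino acid transporter Slc38a5 (7.78-fold, X-linked), Nkx6-3 (at least 3.58-fold) and Etv4, an ETS factor downstream of FGF signalling (2.96-fold). Gad1 had 4.92 ± 0.25 against 8.36 ± 0.22, and its other probes gave log2 differences of -3.34 and -2.78. It was detected on 1 of the 4 arrays of the 2i-derived lines, and with Gad1 and Rhox2a near background in the lower group the size of the fold is uncertain for both.

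In all, 24 of 14569 genes were called, 15 higher and 9 lower in the 2i-derived lines, each at least 2-fold and with groups that did not overlap, and 8 of them lacked a proper symbol. Their adjusted p lay between 0.0472 and 0.0491, just under the threshold of limma's test. The groups did not overlap for 55.7% of genes. Chance gives 33.3% for 4 independent samples and 66.7% if the 2i-derived samples count as 1, and they nearly do by their distance of 0.164, so this share shows no excess. The uncalled genes with the smallest p in each direction had log2 differences of 2.01 (H4c3), 1.33 (Ly6g6e), -1.79 (Ccdc106), -0.83 (G3bp2), -1.48 (Ddx25) and -0.97 (Guk1), while Atp1b2 and Gal, undetected in the 2i-derived lines, stood at least 2.15-fold and at least 2.53-fold lower there. Their adjusted p lay between 0.0515 and 0.0600. At an adjusted p under 0.10 there were 619 genes, 371 higher and 248 lower. X-linked genes made up 121 of the higher and 3 of the lower, while autosomal genes leaned the other way, with 175 higher and 201 lower. The calls ended without background correction, with median scaling and with a robust trend (0 genes by limma, with 3027, 2980 and 3033 at an unadjusted p under 0.05), and 0 genes were called without 2i-RFP+, without 2i-RFP- or with both counted as 1 sample, against 6589 without AFF204#21 and 5328 without R1. In these last 2 fits the spread comes from 2i-RFP+ and 2i-RFP- alone.

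**Figure D1:**
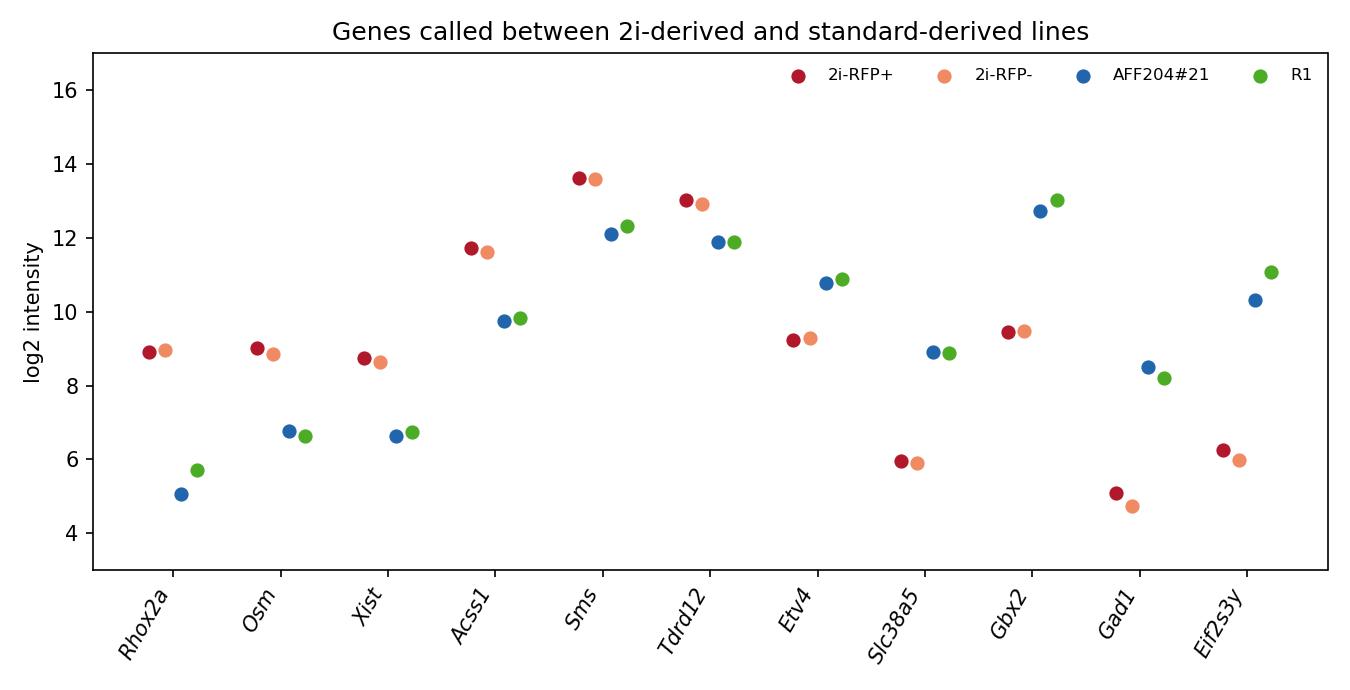
Normalized log2 intensity (vertical axis) of the 11 called genes with a proper symbol that were detected on at least 1 array of both groups, ordered by fold change, with 1 point for each of the 4 samples. Both 2i-derived samples lie together and apart from AFF204#21 and R1 for each gene, from 3.55 log2 units above for Rhox2a to a difference of -4.57 for Eif2s3y.

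X-linked genes stood higher as a class. Over 382 X-linked genes the median log2 difference was 0.603, with 88.0% above 0, against -0.046 over 10377 autosomal genes. It was 0.586 against AFF204#21 alone and 0.567 against R1 alone, and both 2i-derived samples differed by a median of 0.001. Of the genes called higher, 6 were X-linked among 382 and 6 autosomal among 10377 (odds ratio 27.5, Fisher's exact test, two-sided, p = 1.48e-06, over genes, which are not independent replicates). Of the genes called lower, 1 was X-linked (Slc38a5) and 5 autosomal. The Y-linked genes Ddx3y (log2 difference -1.75, adjusted p = 0.123) and Uty (-0.80, adjusted p = 0.212) did not pass the threshold of limma's test, and Ddx3y was 9.28 ± 0.08 in the 2i-derived lines. Ddx3y had -1.19 against AFF204#21 and -2.31 against R1, and Uty -0.46 and -1.14. Among sex markers 1 gene was higher and 1 lower over all genes tested, and 1 and 3 adjusted over the list alone. Among autosomes, chromosome 11 had the lowest median, -0.223 over 884 genes (-0.338 against AFF204#21 and -0.151 against R1), and chromosome 8 the next, -0.143 over 582 genes (-0.033 and -0.267). With autosomal genes alone 1 gene was called, and 3 without chromosomes 8 and 11, choices made after seeing the data.

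**Figure D2:**
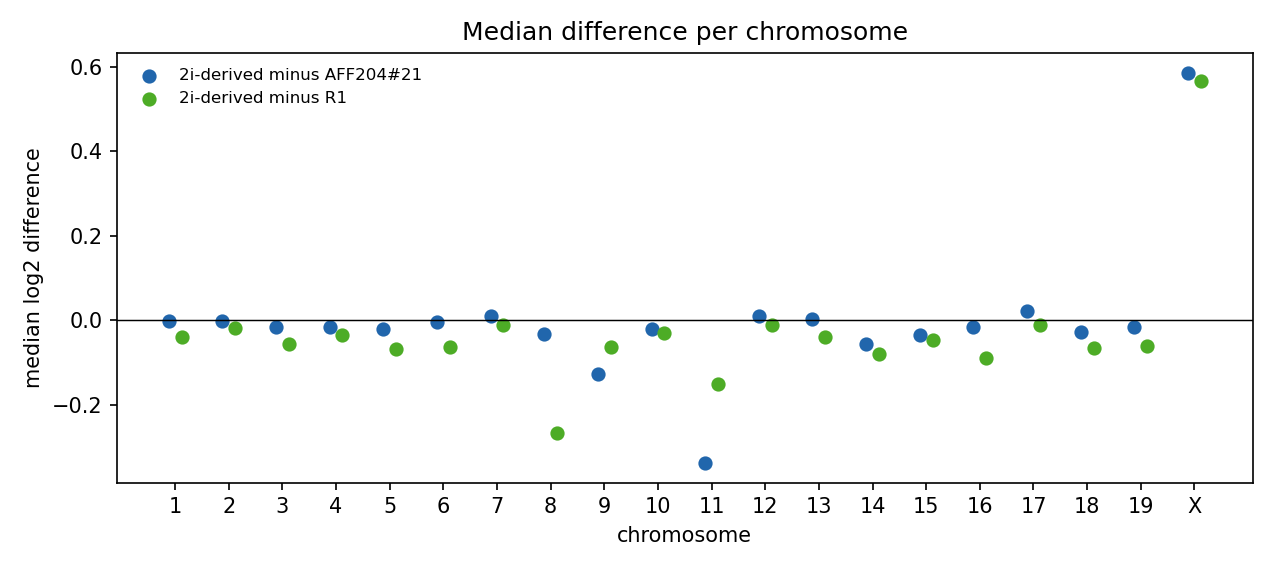
Median log2 difference (vertical axis) of the tested genes of each chromosome (horizontal axis) between the mean of the 2i-derived samples and AFF204#21 (blue) or R1 (green). The X chromosome stands at 0.586 and 0.567, chromosome 11 at -0.338 against AFF204#21 and chromosome 8 at -0.267 against R1.

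Prdm1, which encodes Blimp1, the repressor in the series title that marks primordial germ cell precursors, had a log2 difference of 1.68 ± 0.22 (SE), with 6.76 ± 0.02 (SD, n = 2) in the 2i-derived lines against 5.08 ± 0.38 (n = 2). It did not pass the threshold (adjusted p = 0.0671) and was detected on 1 of the 2 standard-derived arrays. The core pluripotency factors differed little in size: Pou5f1 had a log2 difference of 0.03, Sox2 of 0.26 and Nanog of 0.37 (adjusted p = 0.855, 0.294 and 0.173). Klf4 had -0.87 (adjusted p = 0.127). Zfp42 had -1.49 and a wide spread in the standard-derived group, since R1 stood at 12.83 and the other 3 samples between 9.29 and 9.67, and without R1 the difference was 0.28. Sox2 had -0.04 in the deposited log2 table and -0.05 with the mean of its probes.

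None of the 21 list tests passed with an estimated correlation. Genes of the germline list were higher as a group. Of 19 measured members, 14 lay above 0, with a mean log2 difference of 0.87 and a median of 0.35 (camera adjusted p = 0.00548). No single member was called over all genes, and 4 were higher adjusted over the list alone. These were Prdm1, Rhox5 (1.36), Nanos3 (1.44) and Rhox9 (3.68, with 2.43 against AFF204#21 and 4.93 against R1). Dppa3, a maternal factor and germ cell marker, had 2.21, with 12.26 ± 0.04 against 10.05 ± 1.26 (adjusted p = 0.157), and 1.32 against AFF204#21 and 3.10 against R1. 4 measured members are X-linked, and the list had a mean of 0.49 over its 15 autosomal members (adjusted p = 0.0302). The call was lost with an estimated correlation (adjusted p = 0.685), with fry (0.0709) and over autosomal genes outside chromosomes 8 and 11 (0.106), and over all alternatives the adjusted p ran from 0.000195 to 0.685.

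Feedback genes of MAPK-ERK signalling and target genes of WNT signalling were lower as groups in the 2i-derived lines. Passage number and the level of X-linked genes also parted the groups, so neither can be told apart from derivation here. Of 13 measured feedback genes 1 lay above 0, with a mean log2 difference of -0.56 and a median of -0.63 (camera adjusted p = 0.00187). Etv4 was called, and 5 members were lower adjusted over the list alone, among them Spry4 (-1.34), an inhibitor of receptor tyrosine kinase signalling, Spred1 (-0.63) and Myc (-0.63). Other members, outside the naming rule, differed little in size. These were Dusp6 (-0.12), Dusp4 (-0.13), Fosl1 (-0.20), Ier3 (-0.07), Etv5 (-0.05) and Spred2 (0.045), so the shift did not run through the whole list. Of 8 measured WNT targets 1 lay above 0, with a mean of -0.73 and a median of -0.46 (adjusted p = 0.00187). No target was called over all genes, and 4 were lower adjusted over the list alone: Cdx1 (-1.44), Sp5 (-1.83), the feedback gene Axin2 (-0.98) and Ccnd1 (-0.34). Etv4 and Axin2 lie on chromosome 11, whose median was -0.223. The feedback list kept a mean of -0.56 without chromosomes 8 and 11 (10 members, adjusted p = 0.0115), and the WNT list then had 4 members, too few for the test, with a mean of -0.997. Both calls were lost with an estimated correlation (adjusted p = 0.685 and 0.725) and with fry (0.0709 and 0.173). Over all alternatives the adjusted p ran from 0.000431 to 0.685 for the feedback list and from 2.29e-05 to 0.725 for WNT targets.

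Markers of endoderm and of feeder fibroblasts were lower and targets of p53 higher as groups. The endoderm list had a mean of -0.35 and a median of -0.57 over 11 members, of which 2 lay above 0 (camera adjusted p = 0.0403). No member was called over all genes, and adjusted over the list alone 3 were lower, which were the laminin genes Lama1 (-1.70), Lamc1 (-0.64) and Lamb1 (-0.68). Sox7, an endoderm transcription factor outside the naming rule, went the other way with 1.09 (limma adjusted p = 0.204, second probe 0.70). It had 0.59 against AFF204#21 and 1.60 against R1. Col4a1, a basement membrane collagen, had -0.67, and laminins and this collagen are also made by cells other than endoderm. The feeder list had a mean of -0.27 over 18 members, 2 of them above 0 (adjusted p = 0.0261), with no member called over all genes or adjusted over the list alone. Its first members by p were Tagln (-0.68), Col1a1 (-0.46, adjusted p = 0.175), Acta2 (-0.49) and Pdgfrb (-0.42), and its median was -0.04 against AFF204#21 and -0.41 against R1. The p53 targets had a mean of 0.28 over 13 members, 9 of them above 0 (adjusted p = 0.0261), with no member called over all genes or adjusted over the list alone. Pmaip1, a pro-apoptotic BH3 protein, had 1.77 (1.18 against AFF204#21 and 2.37 against R1), Trp53inp1 0.35 and Bax 0.31. Bbc3 had 0.56, while its other probes gave -0.07 and 0.24. With an estimated correlation all 3 calls were lost (adjusted p = 0.725, 0.806 and 0.685). Leaving out 1 sample also ended calls, the endoderm call without 2i-RFP- (0.0675), AFF204#21 (0.0818) or R1 (0.0701), the feeder call without 2i-RFP- (0.171) or R1 (0.502), and the p53 call without AFF204#21 (0.0553). The calls were also lost with fry (0.173, 0.432 and 0.0978) and over autosomal genes outside chromosomes 8 and 11 (0.173, 0.125 and 0.0535). Over all autosomal genes the endoderm (0.0809) and feeder (0.0652) calls ended, and with the mean of probes the endoderm (0.0522) and p53 (0.0579) calls. The adjusted p ran from 0.00293 to 0.725 for endoderm, from 0.00137 to 0.806 for feeder and from 0.00811 to 0.685 for p53 targets.

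**Figure D3:**
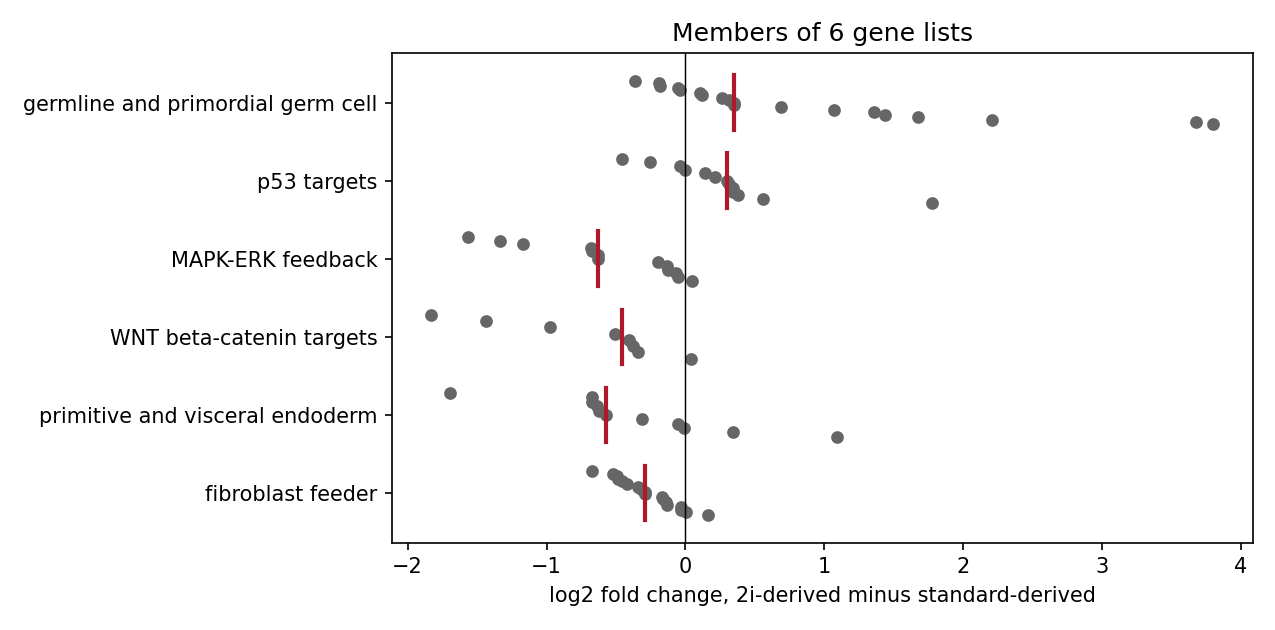
Log2 fold change, 2i-derived minus standard-derived (horizontal axis), of each measured member (grey points) of the 6 called gene lists (vertical axis, points spread for legibility), with the median of each list as a red line. Medians run from 0.351 for germline genes and 0.302 for p53 targets to -0.632 for MAPK-ERK feedback genes.

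The remaining 15 tested lists did not pass the threshold. Mean log2 differences were -0.32 for naive pluripotency (adjusted p = 0.548, with Gbx2 the called member), 0.05 for core pluripotency (0.548), 0.34 for primed epiblast (0.232), -0.05 for trophectoderm (0.936), -0.40 for primitive streak and mesoderm (0.297), -0.21 for LIF-STAT3 targets (0.232), -0.23 for BMP-ID and TGFb-Nodal targets (0.872) and -0.05 for imprinted genes (0.965). They were -0.05 for DNA methylation machinery (0.786), 0.10 for glycolysis and hypoxia (0.240), -0.09 for sterol synthesis (0.592), 0.11 for amino acid and ER stress response (0.294), 0.04 for interferon response and MHC (0.625), -0.17 for the Hox cluster (0.274) and -0.10 for the mitotic cell cycle (0.625). Leaving out 1 sample added calls for naive pluripotency without AFF204#21 (mean -0.60, adjusted p = 0.0496, against -0.05 without R1), for primed epiblast without 2i-RFP- (0.0261) and for amino acid and ER stress response without AFF204#21 (0.0185). Without a detection filter primitive streak and mesoderm (0.0339) and 2-cell-like genes (0.0110) were called. The trophectoderm list had a median of 0.17 and the interferon list a median of -0.08, opposite in sign to their means, and camera ranked the trophectoderm list upward. Beside Gbx2, members that passed adjusted over the list alone and not over all genes included Fgf5 (1.83), a gene of the primed epiblast, Cdx2 (-1.64), Wnt3a (-1.37, detected on 1 of the 4 arrays of the 2i-derived lines), Stat3 (-0.90) and Socs3 (-0.80), Bmp4 (-2.38), the imprinted genes Peg3 (2.25) and Grb10 (-1.78, with -0.65 by its second probe), Pgk1 (0.62), Ifitm1 (0.56) and Irf1 (1.03), and Ccne1 (-0.63). Wnt3a, Stat3, Socs3, Grb10 and Irf1 lie on chromosome 11, and Pgk1 is X-linked, with a value close to the X-linked median of 0.603. The neural ectoderm and 2-cell-like lists had 4 measured members each and are given as values, with means of -0.07 and -1.77. The 2-cell-like value rests on R1, since its mean was -0.54 without R1 and -3.00 without AFF204#21.

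Between 2i-RFP+ and 2i-RFP-, the clearest difference lay in 3 genes of the imprinted Cdkn1c region of chromosome 7. With 1 sample of each there was no replicate check. Cdkn1c, a cyclin-dependent kinase inhibitor, was 2.59-fold higher in 2i-RFP+, Phlda2, which limits placental growth, 2.20-fold and the transporter Slc22a18 2.09-fold. The 4 array pairs gave log2 differences of 1.29 to 1.46, 1.04 to 1.24 and 0.94 to 1.19 for these genes. Of 14580 genes 4 differed at least 2-fold, and the fourth, Cuedc2, rested on 1 array of 2i-RFP+, with an intensity of 9.6 on array A and 1017.6 on array B, against 864 and 914.9 in 2i-RFP-. Next were Ccl4 (0.96), the mesoderm factor T (0.91), Fgf8 (0.88), Wnt8a (0.88) and the WNT target Sp5 (0.85), with Alpk3 (-0.78), Per2 (-0.73), Lonrf1 (-0.65), Birc7 (-0.64) and Dlx3 (-0.64) on the other side. Among the lists, WNT targets had a median of 0.28, Hox genes 0.25, primed epiblast genes 0.16 and feeder fibroblast genes 0.15, all at percentile 100 of matched random lists, and naive pluripotency genes -0.12, at percentile 0. Interferon (percentile 99), LIF-STAT3 (2.23) and germline (2.46) lists were also far out. Members of a list may vary together, which the random lists do not cover, so these percentiles do not show a difference in state. With only the first array of each sample 15 genes differed 2-fold.

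Between AFF204#21 and R1, a pair that differs in strain and passage, genes of the 2-cell-like state stood higher in R1 and trophectoderm genes higher in AFF204#21. Zscan4c, which marks the 2-cell-like state and has near-identical copies, was 18.7-fold and Tcstv3 20.3-fold higher in R1, and 6 of 8 measured list members were at least 2-fold higher there (median -1.17, percentile 0 of matched random lists). The trophectoderm list had a median of 1.21 (percentile 100), with 6 of 10 members at least 2-fold higher in AFF204#21. Over the 9 members tested between the groups, the 2i-derived samples had a median of -0.195 against AFF204#21 and 0.41 against R1. Higher in R1 were also feeder fibroblast genes (median -0.36, percentile 0.05) and naive pluripotency genes (-0.29, percentile 0.02), and higher in AFF204#21 genes of glycolysis and hypoxia (0.21, percentile 99.9) and of amino acid and ER stress response (0.25, percentile 99.8). Zfp42, a naive pluripotency marker, was 11.6-fold and Slc47a1 9.49-fold higher in R1, and AF067061 at least 25.4-fold and Gbp2b at least 15.2-fold. Higher in AFF204#21 were Olig1 (66.2-fold), Ubd (29.8-fold), Cops8 (28.2-fold), Rpgrip1 (16.2-fold), Twistnb (15.9-fold) and Nod1 (11.1-fold), with Apoa2 at least 29.3-fold, Fermt1 at least 12.1-fold and Lrrc57 at least 9.54-fold. Tm7sf3 was 10.9-fold higher by 1 probe, while its second probe gave R1 a log2 difference of -0.17 from the mean of the other 3 samples. Olig1, Ubd, Cops8, Nod1, Fermt1 and Lrrc57 each had 1 detected probe. So did the trophectoderm genes Gata3 (7.808 in AFF204#21, 5.035 in R1) and Krt7 (7.767 and 5.387), both outside the naming rule. For all of these genes a lower level of the RNA in R1 cannot be told from a strain variant under the probe. Among the genes much lower in R1, 20 had a second detected probe. This second probe, by choice the dimmer, showed a median share of 0.16 of the drop, with 0.787 for Twistnb and 1.124 for Apoa2. Of 15284 genes 961 differed at least 2-fold, 538 higher in AFF204#21 and 423 higher in R1, and the count was 621 without background correction, 503 in the deposited log2 table and 526 with strict detection. With 1 sample of each line there was no replicate check.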

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

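The grouping of the 2i-derived samples as 1, the restriction to autosomes and that to autosomes outside chromosomes 8 and 11 were chosen after seeing the data, and the other alternatives before the data were examined. The count of 24 called genes was fragile, since its smallest adjusted p was 0.0472. It became 0 without background correction, 0 with median scaling, 0 with a robust trend, 4 without the trend, 12 in the deposited log2 table, 2 with strict detection, 619 at an adjusted p under 0.10, 0 with the 2i-derived samples counted as 1 (limma, with 802 at an unadjusted p under 0.05), 1 over autosomes and 3 outside chromosomes 8 and 11. Restricting the genes or samples changes what is tested, and the cause of the other changes was not tested. It ran from 0 to 6589 when 1 sample was left out, the lone sample being assumed to vary like the other group. It was 31 without a detection filter, 34 with the mean of probes, 36 with the first array and 24 with a 2-fold minimum. The 16 called genes with a proper symbol kept their direction in all 185 recomputed values. Many of these values could not turn. The groups of these genes did not overlap, so leaving out 1 sample keeps the sign, and dropping the trend leaves the fold change as it was. The 6 called lists became 0 with an estimated correlation, 0 with fry and 1 outside chromosomes 8 and 11, and numbered 4 to 8 otherwise. The count of genes 2-fold apart between AFF204#21 and R1 became 621 without background correction, 503 in the deposited log2 table and 526 with strict detection, and that between 2i-RFP+ and 2i-RFP- became 15 with the first array. The ratio of distances between groups to that within the standard-derived group stayed between 0.972 and 1.04. Signs turned, for a cause not tested, for results that were not called. Sox2 went from 0.26 to -0.044 in the deposited log2 table and -0.051 with the mean of probes. When 1 sample was left out, Pou5f1 ran from -0.042 to 0.103, Zfp42 from -3.26 to 0.28, Ascl2 from -0.084 to 1.07, Hoxb7 from -0.726 to 0.025, Zic1 from -0.22 to 0.09, and the list means of amino acid and ER stress response from -0.045 to 0.266, imprinted genes from -0.21 to 0.10, neural ectoderm from -0.18 to 0.05, interferon response and MHC from -0.022 to 0.105 and trophectoderm from -0.63 to 0.53. Neural ectoderm, with -0.07, had 0.02 in the deposited log2 table, and outside chromosomes 8 and 11 imprinted genes had 0.04 and the interferon list -0.02. With the median in place of the mean the interferon list had -0.075 and the trophectoderm list 0.17. No paired analysis was possible because the samples of both groups share no culture or line.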

Other observations

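The test of matched genes and that of 20 stretches along chromosome 11 were chosen after the shift had been seen. Single imprinted genes had log2 differences between the groups in both directions, while the list had a mean of -0.05 (camera adjusted p = 0.965). Peg3, paternally expressed, had 2.25 log2 units more in the 2i-derived lines and its neighbour Usp29 1.53 (0.35 by its second probe), while Grb10 had -1.78 (-0.65 by its second probe), Phlda2 -1.68 and Igf2 -0.88, and none of these passed the threshold over all genes (adjusted p = 0.0600, 0.141, 0.0824, 0.134 and 0.168). Usp29 had 1.01 against AFF204#21 and 2.05 against R1, Igf2 -1.22 and -0.54, and Phlda2 stood at 11.30 in 2i-RFP+ and 10.16 in 2i-RFP-, so that its value depends on which is left out. Usp29 was detected on 1 of the 2 standard-derived arrays and stood at 4.76 in R1, so the size of its difference is uncertain. Kcnq1ot1, the noncoding RNA of the Cdkn1c region, looked at after its neighbours' values were seen, had a log2 difference of -0.42 between 2i-RFP+ and 2i-RFP-, opposite to Cdkn1c (1.37), Phlda2 (1.14) and Slc22a18 (1.07). Ascl2 had -0.29 (-0.396 to -0.175 over the array pairs), Igf2 0.25 (0.152 to 0.356), H19 0.03, Nap1l4 0.08 and Tssc4 -0.02 in the same comparison. No explanation was tested.

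X-linked genes stood higher in the 2i-derived lines, with an X minus autosome median of 0.62 (95% interval over genes 0.582 to 0.678) against AFF204#21 and 0.627 (0.577 to 0.706) against R1. A strain difference is argued against by the 0.62 found against AFF204#21, which is C57/B6 like the 2i-derived lines, and carry-over of feeder fibroblasts by the median of the feeder list, -0.292 (-0.441 to -0.136), which was -0.043 against AFF204#21 and -0.409 against R1. The values that 2 active X chromosomes in the 2i-derived lines would need are there, the smaller of both medians being 0.62. This value restates the shift to be explained, so it is no separate check, and 2 active X chromosomes remain a hypothesis. Xist, the RNA that coats the inactive X chromosome, was 4.03-fold higher in the 2i-derived lines. Whether this level goes with 2 active X chromosomes was not tested. The Y-linked genes do not settle whether these lines carry a Y, since Eif2s3y had -4.57, Ddx3y -1.75 (adjusted p = 0.123) and Uty -0.80 (adjusted p = 0.212), and they were detected on 4, 4 and 3 of the 4 arrays of the 2i-derived lines, at 6.13, 9.28 and 5.32. The sex of the lines is not in the labels used here, and passage and derivation stay open.

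Genes of chromosome 11 stood lower in the 2i-derived lines than in AFF204#21 and genes of chromosome 8 lower than in R1. A bias that follows expression level is argued against by expression-matched genes of other autosomes, with a median of -0.02 (-0.039 to 0.001) where chromosome 11 had -0.338, and a gain of all of chromosome 11 in AFF204#21 by the first of 5 stretches of neighbouring genes, with 0.048 (0.03 to 0.106). With 20 stretches, the 5 before a border near Arf1 had medians of 0.008 to 0.085 and the 15 past it -0.601 to -0.293, with 0 stretches on the wrong side, which is consistent with extra copies of that part of chromosome 11 in AFF204#21. Such copies do not account for the lower chromosome 11 values against R1, where all 5 stretches, the first included, had medians of -0.207 to -0.118, and these stay open. For chromosome 8 the highest of 5 stretch medians against R1 was -0.191, the value that extra copies of the whole chromosome in at least part of the R1 cells would need, and no karyotype was used here.

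At least 4-fold lower in R1 than in each of the 3 C57/B6 samples were 78 genes, of which 20 had a second detected probe. The second probe showed a median share of 0.16 of the drop (0.043 to 0.669). By the choice of probes it has the lower mean, and near background it could not show a full drop. The level of the second probes was not checked. For 13 of the 20 the second probe showed under 0.5 of the drop, among them Taf6 and Wdr82. A 129 variant under the first probe may account for part of these genes, but a dim second probe would also lower the share. For the other 7, such as Apoa2 and Twistnb, the second probe dropped by at least 0.5 of the amount, which leaves a lower level of the RNA open. Among 40 genes at least 4-fold higher in R1, 3 had a second probe, with a median share of 0.821, and other transcript ends were not tested.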
